A study of Mus musculus with 9 samples.

How the data were processed

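Per the labels, total RNA from the myoblasts, grown in F10 medium with 20% fetal bovine serum and basic fibroblast growth factor at 4 ng/ml, was labelled with biotin and hybridised to Affymetrix mouse gene arrays. The authors deposited log2 intensities after RMA (background subtraction, quantile normalisation and summary of probes into probe sets), made in R 2.10.0. Values ran from 1.93 to 13.2 over 25668 probe sets and 9 arrays, and every column was used. Whether probe sets were filtered before, the genome build and the annotation version are not given in the sources used here.

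Gene names came from the platform's probe annotation. Of the probe sets, 20777 carried 1 gene symbol, 232 carried several and 4659 carried none. The gene identifiers of 20696 probe sets matched those of a RefSeq gene table, and 0 symbols changed. For each of 19661 genes the probe set with the highest mean over the 9 arrays was tested, a choice that mattered for 564 genes with more than 1 probe set. The probe sets for Pax3, Pax7 and Xist were 10355916, 10517715 and 10606178. Genes with near-identical relatives, such as the Prl2c family, the myosin heavy chains and the Y-linked genes with X-linked counterparts, can share signal between probe sets.

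From the deposited values a linear model with a mean per group was fitted over all 9 arrays in limma 3.58.1 under R 4.3.3 (residual df 6, prior df 4.37, prior SD 0.0677), with moderated t-tests and without a trend or robust prior. Genes with a Benjamini-Hochberg adjusted p under 0.05 passed the threshold. Errors of log2 fold changes are moderated standard errors and those of group means are SDs of 3 arrays. Gene lists were tested with camera at its preset correlation of 0.01, with adjusted p over 27 lists. The test, these 27 lists, the rule for naming genes and the alternatives were chosen before the data were examined, except for the alternatives and the 2 further lists that the closing section gives as chosen later. The 27 lists held 796 entries, of which 751 were measured, over 729 distinct genes, and each was written from general knowledge of the pathway or cell type.

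Genes named in the text were chosen by a rule. It names Pax3 and Pax7, and in each comparison the 10 largest rises and 10 largest falls among genes past the threshold whose 3 arrays in each group did not overlap. From each list it names up to 4 members past the threshold with the largest change, or, where none passed, up to 2 with the smallest p. It also names the 5 largest changes shared by both comparisons against control and up to 5 in opposite directions. Clone, locus and predicted symbols, olfactory and vomeronasal receptors, microRNAs, small RNAs and receptor gene segments of lymphocytes were counted and not named. Kdm5d, Kdm5c, Kdm6a, Eif2s3x, Ddx3x, Pbdc1, Myod1, Cdh15, Itga7, Des, Gpnmb, Perp, Krt18, Cxadr and the members of the 2 lists in the closing section lie outside the rule and were named after their values were seen.

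The overlap and correlation from shared controls alone came from 100 simulations (seed 21) of arrays in which no gene changed. They give no expected overlap for lists as long as the real ones. A self-test added known changes to simulated data shaped like the comparison of Pax7 with control. It called 52% of changes of 0.25 log2 units, 98% of 0.5 and 100% of 1 and 2, with 50 genes at each size. Of 19461 unchanged genes, 9 were called (0.0462%). Far more genes passed in the data (8485 for Pax7 against control), which makes the adjusted threshold less strict there. The shares called in the self-test therefore do not give the sensitivity of the real comparison. Of the simulated lists, 1 of 1 shifted by 0.2 log2 units was called by camera, and 0 of the unshifted lists were. Genes were simulated independently, whereas the estimated correlation within a list reached 0.362 (sarcomere list). The self-test could therefore not show false list calls that come from correlated members.

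The first principal component held 83.0% of the variance and separated the control arrays (scores of -50.2 to -47.6) from the Pax3 (17.0 to 17.8) and Pax7 arrays (30.8 to 32.0). The second held 10.3%. The median SD over genes was 0.0552 in control, 0.0766 in Pax3 and 0.0474 in Pax7 arrays.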

Results

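Gene expression was measured in cultured mouse myoblasts, the dividing precursor cells of skeletal muscle, of Balb/c background. Total RNA from 3 groups of cells was hybridised to 9 biotin-labelled arrays, 3 per group: cells with an empty vector (control), cells overexpressing Pax3 and cells overexpressing Pax7. Pax3 and Pax7 are paralogous paired-box transcription factors of the muscle lineage. Pax3 acts mainly in muscle precursors of the embryo, and Pax7 marks satellite cells, the stem cells of adult muscle. Values were log2 intensities per probe set, with array medians between 6.397 and 6.477, and the number of arrays limited their precision. Arrays of a group correlated at r = 0.997 to 0.999 across probe sets, which are not independent replicates. Control and Pax3 arrays correlated at r = 0.9754 to 0.9774, control and Pax7 arrays at 0.967 to 0.970, and Pax3 and Pax7 arrays at 0.993 to 0.994. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which can be technical. The design asked how each factor changed gene expression in myoblasts and where the factors differed from each other.

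The overexpressed genes followed their labels. Pax3 stood at a log2 intensity of 5.83 ± 0.071 in control arrays (SD, n = 3), 11.05 ± 0.046 in Pax3 arrays and 6.82 ± 0.039 in Pax7 arrays. It was 37.2-fold higher in Pax3 than in control arrays (limma adjusted p = 2e-13). Pax7 was already high in control myoblasts, at 10.51 ± 0.081, reached 12.28 ± 0.030 in Pax7 arrays and was 8.18 ± 0.065 in Pax3 arrays (SD, n = 3 each). It was 3.40-fold higher in Pax7 than in control arrays and 5.02-fold lower in Pax3 than in control arrays (limma adjusted p = 4.04e-10 and 9.86e-11). The probe sets could not separate transcripts of the cells' own genes from those of the introduced constructs. Pax3 and Pax7 are similar in sequence, so the 1.99-fold higher Pax3 signal in Pax7 arrays can include signal from Pax7 transcripts.

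Sex-linked genes split the control arrays from all Pax3 and Pax7 arrays. Xist, the noncoding RNA made from the inactive X chromosome of female cells, stood at 4.77 ± 0.126 in control arrays, 11.96 ± 0.071 in Pax3 arrays and 11.72 ± 0.033 in Pax7 arrays (SD, n = 3 each). The Y-linked genes Eif2s3y, Uty and Kdm5d stood at 8.78 ± 0.040, 9.27 ± 0.094 and 8.31 ± 0.025 in control arrays. The same genes lay at 3.12 ± 0.019, 3.85 ± 0.085 and 4.24 ± 0.162 in Pax3 arrays and at 3.08 ± 0.014, 3.77 ± 0.097 and 4.29 ± 0.037 in Pax7 arrays. Each of the 2 comparisons against control was therefore also a comparison of arrays without Y-linked transcripts against arrays with them, while the comparison of Pax7 with Pax3 was not. Between Pax7 and Pax3 arrays, Xist differed by -0.24 ± 0.064 (limma adjusted p = 0.0262), a call that ended when any of 5 single arrays was left out (adjusted p up to 0.106).

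**Figure D1:**
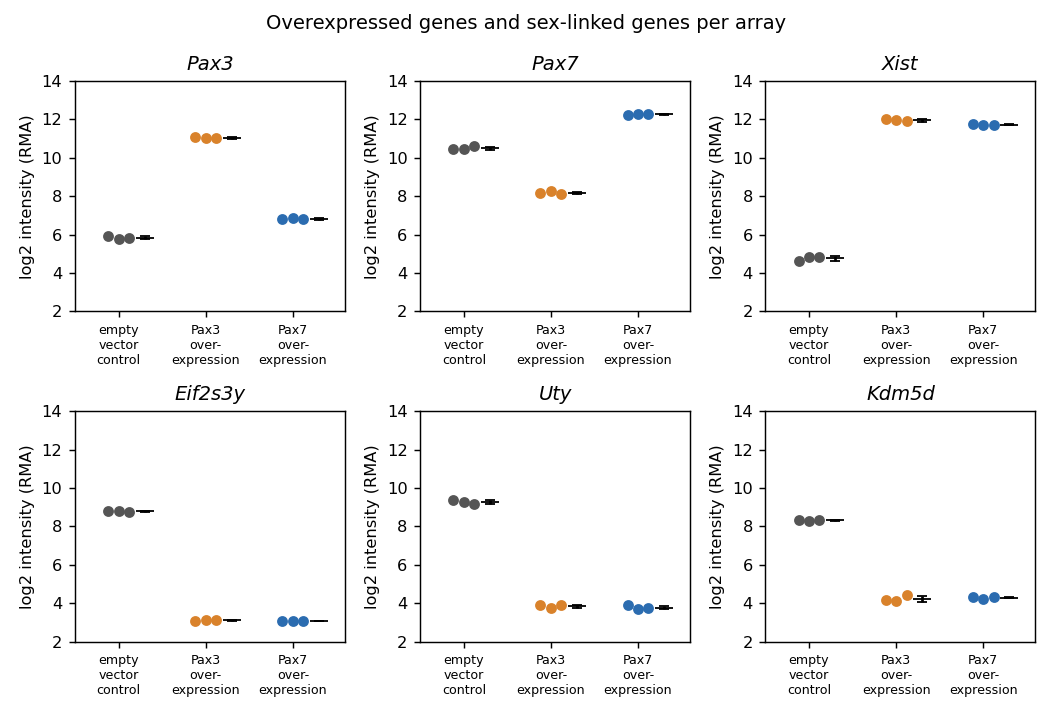
Log2 intensity (RMA, vertical axis) of Pax3, Pax7, Xist, Eif2s3y, Uty and Kdm5d in the 3 arrays of each group (horizontal axis); coloured points are arrays, and black bars are the group mean ± SD. Xist lies near 4.77 in control arrays and above 11 in all Pax3 and Pax7 arrays, and the Y-linked Eif2s3y, Uty and Kdm5d lie the other way round.

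In Pax3-overexpressing myoblasts, most genes of the contractile apparatus fell. Of 63 measured sarcomere and contraction genes of differentiated muscle, 52 fell, 4 rose and 7 did not pass, with a median log2 fold change of -1.07; adjusted over the list alone, 57 passed. Myh1, a myosin heavy chain of fast fibres, was 17.6-fold lower (log2 fold change -4.14 ± 0.136, SE, n = 3 per group), slow troponin T Tnnt1 changed by -3.15 ± 0.074, muscle creatine kinase Ckm by -2.80 ± 0.046 and triadin Trdn by -2.71 ± 0.084. The list passed camera downward (adjusted p = 6.35e-20), and adjusted p = 0.157 with an estimated correlation. Among the myogenic transcription factors, Myf5, which acts at the start of myogenic commitment, was 3.92-fold higher (1.97 ± 0.056), while the differentiation factors Myog (-1.30 ± 0.066) and Mef2c (-1.29 ± 0.090) were lower. The control arrays carried the Y-linked transcripts and the Pax3 arrays Xist, so these shifts moved together with the sex-linked genes.

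The test found 7780 of 19661 genes past the threshold between Pax3 and control arrays (39.6%, limma adjusted p under 0.05), 3902 higher and 3878 lower. Of these, 944 changed by at least 1 log2 unit, 451 upward and 493 downward, and 3264 exceeded a fold change of 1.2 in limma's treat test. In 8859 genes (45.1%) the 3 arrays of each group did not overlap, against 10% by chance. Apart from Xist and Pax3, the largest rises were in Prl2c5 (6.34 ± 0.138), a placental hormone gene of the prolactin family with near-identical relatives that can share its signal, and in the neurofilament light chain Nefl (5.68 ± 0.068). Next came the collagen receptor subunit Itga2 (4.90 ± 0.051), mesothelin Msln (4.66 ± 0.054), the desmosome component Dsp (4.57 ± 0.107), Epb41l4a (4.47 ± 0.047), Niban1 (4.34 ± 0.068) and the transcription factor Sim2 (4.15 ± 0.072). The largest falls, besides Eif2s3y, Uty and Myh1, were in the chemokine Cxcl13 (-6.25 ± 0.053), neuritin Nrn1 (-4.97 ± 0.092), the metalloproteinase inhibitor Timp3 (-4.77 ± 0.094), Prr32 (-4.69 ± 0.082), the splicing regulator Rbfox1 (-4.22 ± 0.059), Islr (-4.14 ± 0.046) and Asb4 (-4.10 ± 0.064). Log2 fold changes of the 118 genes chosen by the naming rule had standard errors of 0.0370 to 0.150 and limma adjusted p of at most 0.0229.

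Genes tied to muscle identity moved mostly downward in Pax3 arrays. Of 20 myogenic transcription factors, 5 rose, 13 fell and 2 did not pass (20 passed adjusted over the list alone), with the clock-linked repressor Bhlhe41 at -1.12. For the myogenic factors, camera gave adjusted p = 0.0083, and adjusted p = 0.244 with an estimated correlation. Satellite cell surface and quiescence markers gave 6 rises, 13 falls and 6 genes not past among 25 (19 adjusted over the list alone), with Sox8 at -1.86, the growth factor receptor Fgfr4 at -1.46, Cd82 at -1.16 and Vcam1 at 0.88. For the satellite cell list, camera gave adjusted p = 0.0107, and adjusted p = 0.244 with an estimated correlation. In the list of dermomyotome and limb muscle precursor genes, a setting in which Pax3 acts in the embryo, 3 rose, 12 fell and 11 of 26 did not pass (15 adjusted over the list alone). Dmrt2 (-2.51), Tbx15 (-1.81) and Tbx1 (-1.22) were among those that fell. For the dermomyotome list, camera gave adjusted p = 0.0107, and adjusted p = 0.098 with an estimated correlation. Smooth muscle and stress fibre genes gave 4 rises and 10 falls among 19, with 5 not past and 14 past adjusted over the list alone, and Csrp2 (-2.88), Cnn1 (-2.46), Synpo2 (-1.69) and Tagln (-1.60) fell furthest. The smooth muscle list passed camera (adjusted p = 0.00552, and adjusted p = 0.147 with an estimated correlation), but not without the lowest 50% of genes by mean intensity (adjusted p = 0.158).

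Signalling, positional and growth lists also fell in Pax3 arrays. Of 25 Id and Notch pathway genes, 14 fell, 2 rose and 9 did not pass (17 adjusted over the list alone), with the Notch targets Hey1 (-2.97) and Heyl (-2.10), the ligand Dll1 (-2.18) and the receptor Notch3 (-1.87) lower. For Id and Notch genes, camera gave adjusted p = 4.86e-05, and adjusted p = 0.098 with an estimated correlation. In the Wnt list, 3 rose, 14 fell and 14 of 31 did not pass (17 adjusted over the list alone): the secreted regulators Sfrp2 (-3.25) and Rspo3 (-1.57) and the nuclear effector Lef1 (-1.33) fell, while the ligand Wnt5a rose by 2.77. For the Wnt list, camera gave adjusted p = 0.00671, and adjusted p = 0.248 with an estimated correlation. Among 35 Hox genes, which mark position along the body axis, 20 fell, 8 rose and 7 did not pass (28 adjusted over the list alone). Hoxb2 (-1.39) and Hoxa11 (-1.27) fell and Hoxd8 (3.66) and Hoxc8 (1.73) rose. For Hox genes, camera gave adjusted p = 0.0107, and adjusted p = 0.098 with an estimated correlation. Imprinted growth genes numbered 14 falls, 3 rises and 6 not past among 23 (17 adjusted over the list alone). Necdin Ndn (-2.74) and the fetal growth factor Igf2 (-1.34) fell and Grb10, an inhibitor of growth factor receptors, rose by 3.38. For imprinted genes, camera gave adjusted p = 0.00157, and adjusted p = 0.098 with an estimated correlation. Of 27 S phase genes, 16 fell, 4 rose and 7 did not pass (20 adjusted over the list alone), among them cyclin E2 Ccne2 (-0.93) and the replicative helicase subunit Mcm4 (-0.83) downward and Chaf1b (0.75) upward. For S phase genes, camera gave adjusted p = 0.0037, and adjusted p = 0.315 with an estimated correlation. Cholesterol synthesis genes gave 15 falls, 3 rises and 1 gene not past among 19 (19 adjusted over the list alone). Insig1 (-1.53), Hmgcs1 (-1.32), Cyp51 (-1.31) and Stard4 (-1.25) led the falls. For cholesterol synthesis, camera gave adjusted p = 1.48e-05, and adjusted p = 0.176 with an estimated correlation.

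The 4 lists that passed upward in Pax3 arrays concerned metabolism, stress and interferon. Of 22 hypoxia and glycolysis genes, 18 rose, 1 fell and 3 did not pass (20 adjusted over the list alone), including Ndrg1 (2.30), the oxygen sensor Egln3 (1.99), hexokinase Hk2 (1.97) and the glucose transporter Slc2a3 (1.38); camera gave adjusted p = 3.85e-08, and adjusted p = 0.098 with an estimated correlation. Unfolded protein and amino acid stress genes gave 18 rises, 2 falls and 10 not past among 30 (22 adjusted over the list alone), with the cysteine synthesis enzyme Cth (2.45), Trib3 (1.52), Vldlr (1.47) and the stress factor Ddit3 (1.36) higher. For the stress list, camera gave adjusted p = 0.000286, and adjusted p = 0.315 with an estimated correlation. In the interferon response list, 14 rose, 1 fell and 15 of 30 did not pass (16 adjusted over the list alone); Ifit1 (1.69), Rtp4 (1.45) and Ifih1 (0.84) rose and Isg20 was at -1.03. That list passed camera (adjusted p = 0.00635, and adjusted p = 0.098 with an estimated correlation), but not without the lowest 50% of genes (adjusted p = 0.256). Adipocyte genes gave 9 rises, 2 falls and 10 not past among 21 (11 adjusted over the list alone), with the fatty acid receptor Cd36 (1.19) and the adipocyte regulator Pparg (1.12) up and Cebpa (-1.18) down. For adipocyte genes, camera gave adjusted p = 0.00671, and adjusted p = 0.179 with an estimated correlation.

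The other 12 lists did not pass camera between Pax3 and control arrays (adjusted p from 0.214 to 0.908), though single members changed. Without the lowest 50% of genes, neuronal and glial (adjusted p = 0.00533), macrophage and leukocyte (0.0282) and bone and cartilage genes (0.0396) did pass. Growth factor signalling and MAPK feedback genes gave 14 rises, 17 falls and 8 not past among 39 (32 adjusted over the list alone), with the epidermal growth factor receptor Egfr (3.15), Fgfr2 (2.76) and the ligand Ereg (2.05) up and Igfbp5 (-2.99) down. BMP and TGF-beta genes gave 10 rises and 14 falls among 32 (24 adjusted over the list alone), with the secreted antagonists follistatin Fst at -3.24 and gremlin Grem1 at 2.12, and the ligands Bmp4 at 1.72 and Tgfb3 at -1.60. Basement membrane and integrin genes numbered 14 rises and 9 falls of 32 (23 adjusted over the list alone), fibroblast and extracellular matrix genes 9 and 12 of 36 (21), and cyclins, Cdk inhibitors and growth arrest genes 7 and 11 of 25 (19). Among these, Itga1 (1.06), Tnc (2.23), Fbln2 (2.39) and the cell cycle inhibitor Cdkn2a (1.42) rose and Postn (-2.58) and Gas1 (-1.74) fell. G2 and M phase genes gave 4 rises and 5 falls of 30 (9), inflammatory cytokine and NF-kappaB genes 9 and 6 of 28 (15), and neural crest and melanocyte genes 5 and 5 of 25 (10). Neuronal and glial genes gave 7 and 2 of 28 (8), bone and cartilage genes 2 and 5 of 22 (7), endothelial genes 2 and 0 of 18 (2), and macrophage and leukocyte genes 2 and 0 of 20 (2). Examples were Nfkbia (-1.01), Nrcam (1.51), Nefm (3.80), the osteoblast factor Sp7 (-2.40), Egfl7 (0.63), Laptm5 (2.08) and Cd68 (1.36). The median and mean log2 fold change had different signs in the growth factor (-0.0731 and 0.0708), fibroblast (0.0112 and -0.163) and neural crest (0.0281 and -0.00193) lists, all 3 of which camera placed downward. Of the 15 lists past camera, 0 passed with an estimated correlation (8 of 27 at an unadjusted p under 0.05), while fry, which tests each list on its own, passed 22 of 27 and placed the growth factor list upward (adjusted p = 0.161).

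**Figure D2:**
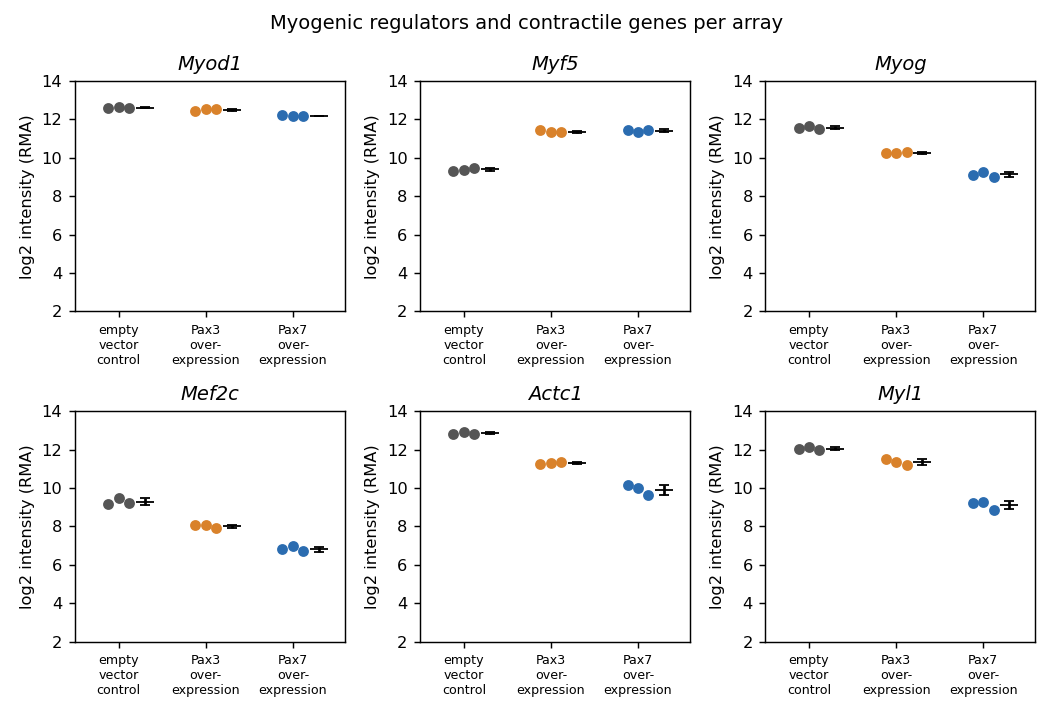
Log2 intensity (RMA, vertical axis) of Myod1, Myf5, Myog, Mef2c, Actc1 and Myl1 in the 3 arrays of each group (horizontal axis); coloured points are arrays, and black bars are the group mean ± SD. Myf5 is near 9.40 in control and above 11 in Pax3 and Pax7 arrays, while Myog falls from 11.57 in control to 10.27 in Pax3 and 9.13 in Pax7 arrays.

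Pax7-overexpressing myoblasts showed the largest fall of contractile genes. Of the 63 sarcomere and contraction genes, 55 fell, 3 rose and 5 did not pass, with a median log2 fold change of -1.72; adjusted over the list alone, 61 passed. Myh1 changed by -4.25 ± 0.136 (SE, n = 3 per group), Tnnt1 changed by -3.84 ± 0.074, the giant thin-filament protein nebulin Neb by -3.41 ± 0.062 and Klhl41 by -3.38 ± 0.092. For contractile genes, camera gave adjusted p = 1.34e-28, and adjusted p = 0.108 with an estimated correlation. Mef2c and Myog were 5.56-fold and 5.40-fold lower (-2.48 ± 0.090 and -2.43 ± 0.066), and Myf5 was 4.05-fold higher (2.02 ± 0.056). Myod1, a master regulator of myogenesis named here after its values were seen, changed by -0.43 ± 0.043 against control in Pax7 arrays (limma adjusted p = 8.68e-06) and by -0.12 ± 0.043 in Pax3 arrays (adjusted p = 0.053). Bmp4, a secreted signal that restrains myogenic differentiation, was 42.1-fold higher (5.40 ± 0.094) and Bmp6 14.3-fold higher (3.83 ± 0.058). As in the Pax3 comparison, the control arrays held the Y-linked transcripts and the Pax7 arrays Xist.

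Between Pax7 and control arrays 8485 genes passed (43.2%, limma adjusted p under 0.05), 4253 higher and 4232 lower. A change of at least 1 log2 unit was seen in 1294 of them, 647 in each direction, and 3819 exceeded a fold change of 1.2 in the treat test. Groups did not overlap in 10907 genes (55.5%), against 10% by chance. Prl2c5 (6.97 ± 0.138), Nefl (5.62 ± 0.068), Epb41l4a (4.99 ± 0.047), Itga2 (4.96 ± 0.051), Dsp (4.83 ± 0.107), Msln (4.82 ± 0.054), Niban1 (4.68 ± 0.068) and the fatty acid elongase Elovl7 (4.45 ± 0.071) rose most after Xist and Bmp4. The muscle and fat enzyme carbonic anhydrase Car3 fell most (-6.30 ± 0.091), followed, apart from Eif2s3y, Uty and Myh1, by Cxcl13 (-6.19 ± 0.053), Nrn1 (-5.30 ± 0.092), Timp3 (-4.88 ± 0.094), Prr32 (-4.84 ± 0.082), Asb4 (-4.77 ± 0.064) and Islr (-4.58 ± 0.046). The 120 genes chosen by the rule had standard errors of 0.0387 to 0.150 and limma adjusted p of at most 0.0316.

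Muscle and developmental lists fell in Pax7 arrays. Myogenic transcription factors gave 5 rises, 13 falls and 2 not past of 20 (20 adjusted over the list alone), with the transcriptional cofactor Eya1 at -1.53. For the myogenic factors, camera gave adjusted p = 0.00212, and adjusted p = 0.19 with an estimated correlation. Satellite cell markers, the adult cell type in which Pax7 acts, gave 7 rises, 13 falls and 5 not past of 25 (20 adjusted over the list alone). Fgfr4 (-2.28), Sox8 (-1.61), Cav1 (-1.37) and Cd82 (-1.32) were the members that moved most. For the satellite cell list, camera gave adjusted p = 0.0125, and adjusted p = 0.224 with an estimated correlation. In the smooth muscle and stress fibre list, 3 rose, 11 fell and 5 of 19 did not pass (14 adjusted over the list alone), led by Tagln (-3.20), Csrp2 (-3.18), Cnn1 (-2.55) and Synpo2 (-2.39). Camera passed it (adjusted p = 0.00126, and adjusted p = 0.108 with an estimated correlation), but not without the lowest 50% of genes (adjusted p = 0.066). Hox genes gave 7 rises, 19 falls and 9 not past of 35 (27 adjusted over the list alone), with Hoxd8 at 2.89, Hoxc8 at 1.28, Hoxb2 at -1.31 and Hoxa11 at -1.17. For Hox genes, camera gave adjusted p = 0.0121, and adjusted p = 0.108 with an estimated correlation. Id and Notch genes gave 5 rises, 15 falls and 5 not past of 25 (21 adjusted over the list alone), with Hey1 at -3.10, Dll1 at -2.68, Heyl at -2.07 and Notch3 at -1.95. For Id and Notch genes, camera gave adjusted p = 0.00127, and adjusted p = 0.108 with an estimated correlation. In the Wnt list, 3 rose, 12 fell and 16 of 31 did not pass (16 adjusted over the list alone); Sfrp2 (-3.42), Lef1 (-1.59) and Tcf7l2 (-1.50) fell and Wnt5a rose by 2.56. The Wnt call (camera adjusted p = 0.0276, and adjusted p = 0.339 with an estimated correlation) ended when only the groups compared entered the fit (adjusted p = 0.0615) and without the lowest 25% of genes (adjusted p = 0.087).

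Growth and metabolic lists moved in Pax7 arrays as follows. Imprinted growth genes gave 5 rises, 13 falls and 5 not past of 23 (18 adjusted over the list alone), with Ndn at -3.06, the retrotransposon-derived Peg10 at -2.22 and Grb10 at 2.45. For imprinted genes, camera gave adjusted p = 0.00205, and adjusted p = 0.108 with an estimated correlation. S phase genes gave 3 rises, 17 falls and 7 not past of 27 (20 adjusted over the list alone), with Mcm4 at -0.92, Ccne2 at -0.84, Rfc4 at -0.69 and Chaf1b at 0.92. For S phase genes, camera gave adjusted p = 0.00158, and adjusted p = 0.283 with an estimated correlation. Cholesterol synthesis genes gave 3 rises, 15 falls and 1 not past of 19 (18 adjusted over the list alone), with Cyp51 and Insig1 both at -1.34 and Hmgcs1 at -1.15. For cholesterol synthesis, camera gave adjusted p = 0.000485, and adjusted p = 0.219 with an estimated correlation. Of 22 hypoxia and glycolysis genes, 18 rose, 0 fell and 4 did not pass (19 adjusted over the list alone), with Slc2a3 20.0-fold higher (4.32 ± 0.056) and Ndrg1 (2.46), Egln3 (2.18) and Hk2 (1.85) also up. For hypoxia and glycolysis, camera gave adjusted p = 8.86e-08, and adjusted p = 0.108 with an estimated correlation. Unfolded protein and amino acid stress genes gave 15 rises, 4 falls and 11 not past of 30 (21 adjusted over the list alone), with Cth at 2.11, the cystine transporter Slc7a11 at 1.55, Trib3 at 1.49 and Ddit3 at 1.34. For the stress list, camera gave adjusted p = 0.00762, and adjusted p = 0.44 with an estimated correlation. Interferon response genes gave 16 rises, 1 fall and 13 not past of 30 (17 adjusted over the list alone), with Isg20 at 1.07, Ifit1 at 1.06 and Stat2 at 0.74. For the interferon list, camera gave adjusted p = 0.0193, and adjusted p = 0.137 with an estimated correlation. Adipocyte genes gave 11 rises, 2 falls and 8 not past of 21 (14 adjusted over the list alone), with Pparg at 1.33, the lipid droplet protein Plin2 at 1.08 and Cebpa at -1.05. For adipocyte genes, camera gave adjusted p = 0.0088, and adjusted p = 0.192 with an estimated correlation.

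The remaining 13 lists did not pass camera between Pax7 and control arrays (adjusted p from 0.0507 to 0.896). Dermomyotome and limb muscle precursor genes, the nearest to the threshold, gave 6 rises, 12 falls and 8 not past of 26 (20 adjusted over the list alone), with Tbx15 at -2.69 and Dmrt2 at -1.99. This list passed camera without control replicate 1, Pax3 replicate 3 or Pax7 replicate 1 or 2 (adjusted p = 0.0354 to 0.0476). Growth factor genes gave 16 rises and 14 falls of 39 (30 adjusted over the list alone), with Egfr at 3.23, Fgfr2 at 3.20 and Igfbp5 at -2.65. BMP and TGF-beta genes gave 12 and 14 of 32 (27), basement membrane and integrin genes 13 and 11 of 32 (24), fibroblast and extracellular matrix genes 9 and 13 of 36 (24), and cyclins, Cdk inhibitors and growth arrest genes 8 and 13 of 25 (21). In these, Fst (-2.43), Postn (-3.58), Gas1 (-2.30) and Btg2 (-1.81) fell and Itgb4 (2.67), Tnc (2.17) and Cdkn2a (1.58) rose. G2 and M phase genes gave 2 rises and 11 falls of 30 (13), with the proliferation marker Mki67 at -0.45 and the spindle motor Kif11 at -0.40. They passed camera with only the compared groups in the fit (adjusted p = 0.0345), with array weights (0.0474) and without Pax3 replicate 2 or 3 or Pax7 replicate 1 (0.0334 to 0.0471). Without the lowest 50% of genes, neuronal and glial (adjusted p = 0.0182), macrophage and leukocyte (0.0329) and bone and cartilage genes (0.0473) passed. Inflammatory cytokine genes gave 9 and 4 of 28 (13), neural crest genes 3 and 5 of 25 (8), neuronal and glial genes 7 and 3 of 28 (10), and bone and cartilage genes 2 and 5 of 22 (7). Endothelial genes gave 3 and 0 of 18 (3) and macrophage and leukocyte genes 3 and 1 of 20 (3). Il33 (2.78), Nrcam (1.95), Stmn2 (3.04), the cartilage proteoglycan Acan (2.09), Egfl7 (1.05) and Cd68 (2.04) rose, and Cxcl12 (-1.49) and Sp7 (-2.31) fell. Median and mean had different signs in the BMP (-0.114 and 0.118), fibroblast (0.000946 and -0.35) and bone (0.0278 and -0.0812) lists, and the neural crest list, with both above 0 (0.0419 and 0.000707), was placed downward by camera. Of the 14 lists past camera, 0 passed with an estimated correlation (8 of 27 at an unadjusted p under 0.05). Fry passed 25 of 27 and called the BMP list upward (adjusted p = 0.00365), where camera placed it downward without a call (adjusted p = 0.359).

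**Figure D3:**
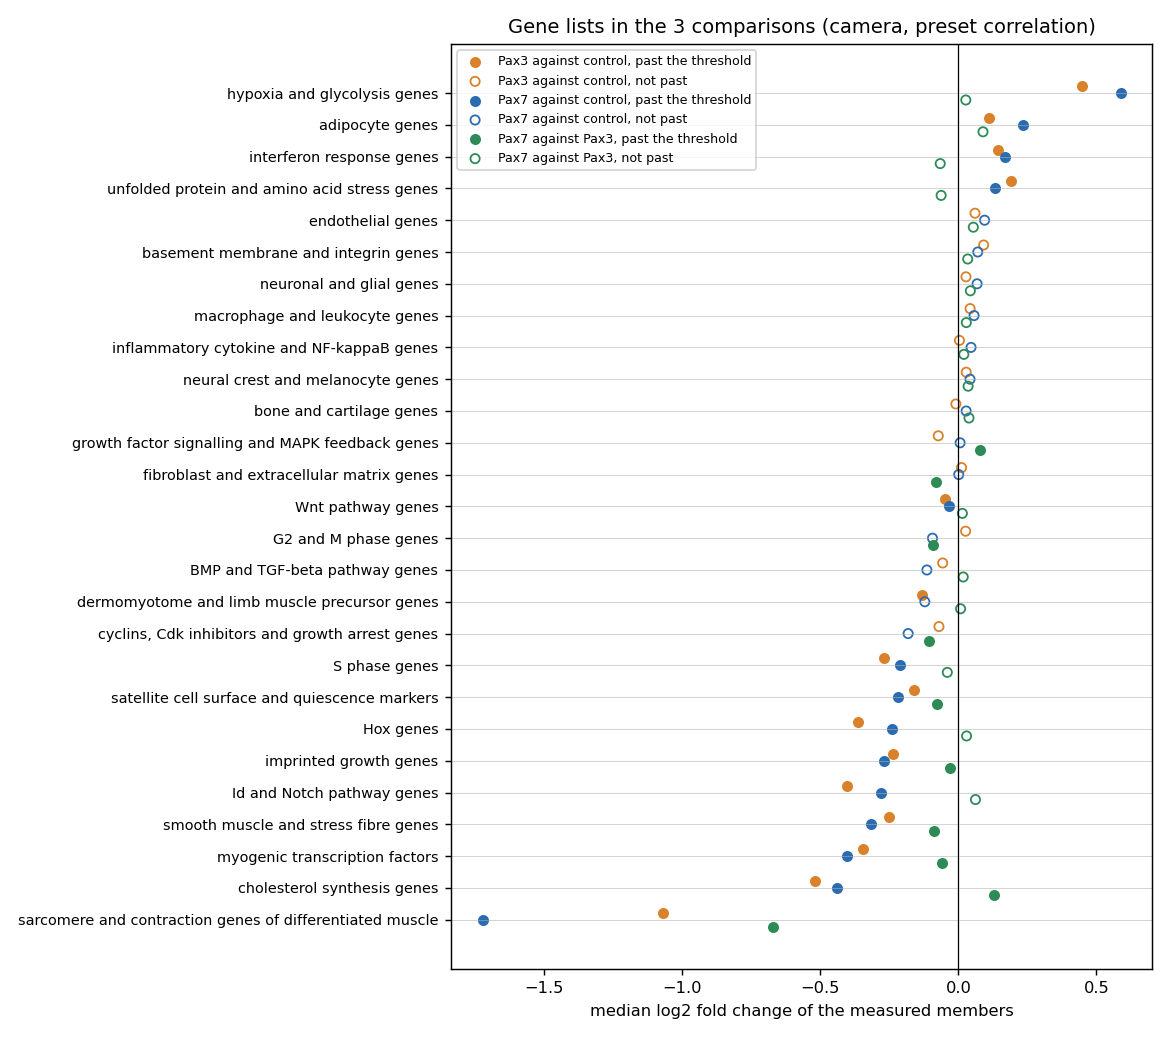
Median log2 fold change (horizontal axis) of the measured members of each of 27 gene lists (vertical axis) in the 3 comparisons, by colour; filled circles passed camera with a preset correlation (adjusted p under 0.05), and open circles did not. The sarcomere list lies lowest, at -1.07 for Pax3 and -1.72 for Pax7 against control and -0.67 for Pax7 against Pax3, and the hypoxia and glycolysis list highest against control, at 0.45 and 0.59.

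Compared directly with Pax3 arrays, Pax7 arrays had lower contractile genes and higher Bmp4 and Bmp6. Of the 63 sarcomere and contraction genes, 49 fell, 0 rose and 14 did not pass, with a median of -0.67; adjusted over the list alone, 50 passed. The fast light chain Myl1 was 4.70-fold lower (-2.23 ± 0.106, SE, n = 3 per group), Smpx changed by -1.42 ± 0.115, the calcium store protein Casq2 by -1.41 ± 0.097 and the developmental actin Actc1 by -1.40 ± 0.104. For contractile genes, camera gave adjusted p = 6.38e-35, and adjusted p = 0.144 with an estimated correlation. Bmp4 was 12.8-fold higher in Pax7 than in Pax3 arrays (3.68 ± 0.094) and Bmp6 6.42-fold higher (2.68 ± 0.058). Mef2c and Myog were lower by -1.18 ± 0.090 and -1.14 ± 0.066. Myf5 differed by 0.05 (95% confidence interval -0.0751 to 0.171, limma adjusted p = 0.662).

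In this comparison 3316 genes passed (16.9%, limma adjusted p under 0.05), 1637 higher and 1679 lower in Pax7 arrays. Of these, 176 differed by at least 1 log2 unit, 111 upward and 65 downward; 784 exceeded a fold change of 1.2 in the treat test, 2107 passed an adjusted p under 0.01, and weighting the arrays by their estimated quality gave 5348. Groups did not overlap in 5771 genes (29.4%), against 10% by chance. After Pax7 and Bmp4, the largest differences upward were in the amino acid transporter Slc7a8 (2.98 ± 0.099), the Wnt amplifier Rspo1 (2.97 ± 0.065), Slc2a3 (2.94 ± 0.056), the neuronal membrane protein Gpm6a (2.93 ± 0.060), the zinc receptor Gpr39 (2.78 ± 0.049), the protease Klk14 (2.69 ± 0.123), Bmp6 and Entpd3 (2.52 ± 0.062). Downward, after Pax3, came Car3 (-2.59 ± 0.091), the thyroid hormone-activating deiodinase Dio2 (-2.26 ± 0.060), Myl1, Iqsec3 (-1.64 ± 0.058), Tagln (-1.59 ± 0.055) and Srpx2 (-1.48 ± 0.062). The 109 genes chosen by the rule had standard errors of 0.0395 to 0.130 and limma adjusted p of at most 0.0435.

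Myogenic and mesenchymal lists were lower in Pax7 than in Pax3 arrays. Of 20 myogenic transcription factors, 8 fell, 0 rose and 12 did not pass (8 adjusted over the list alone), with Eya1 at -0.74 and Bhlhe41 at -0.39. For the myogenic factors, camera gave adjusted p = 0.000714, and adjusted p = 0.197 with an estimated correlation. Smooth muscle and stress fibre genes gave 1 rise, 7 falls and 11 not past of 19 (9 adjusted over the list alone), with Myl9 at -1.13, Synpo2 at -0.69 and the smooth muscle actin Acta2 at -0.66. For the smooth muscle list, camera gave adjusted p = 3.96e-05, and adjusted p = 0.104 with an estimated correlation. Fibroblast and extracellular matrix genes gave 4 rises, 11 falls and 21 not past of 36 (17 adjusted over the list alone), with Fbln2 at -1.20, Loxl1 at -0.97 and the gelatinase Mmp2 at -0.95. For the fibroblast list, camera gave adjusted p = 0.000673, and adjusted p = 0.104 with an estimated correlation. Growth arrest genes and cyclins gave 1 rise, 8 falls and 16 not past of 25 (12 adjusted over the list alone), with Gas1 at -0.56, Gadd45g at -0.40, Cdkn2c at -0.36 and the retinoblastoma gene Rb1 at -0.36. For the growth arrest list, camera gave adjusted p = 0.00148, and adjusted p = 0.164 with an estimated correlation. G2 and M phase genes gave 0 rises, 5 falls and 25 not past of 30 (5 adjusted over the list alone), with a median of -0.0915. Of these falls, Hmmr, Cenpf and Nek2 lost their calls without Pax7 replicate 2 (limma adjusted p = 0.155, 0.0737 and 0.0669). The same genes also lost them without Pax7 replicate 1 or Pax3 replicate 2. With only the compared groups in the fit, their limma adjusted p was 0.101, 0.0541 and 0.0561. Hmmr also lost its call without any single control array (0.0585 to 0.0613), and Racgap1 without Pax7 replicate 3 (0.0558). For G2 and M phase genes, camera gave adjusted p = 0.000215, and adjusted p = 0.542 with an estimated correlation. Cholesterol synthesis genes gave 7 rises, 0 falls and 12 not past of 19 (7 adjusted over the list alone), with Msmo1 at 0.54, Tm7sf2 at 0.46 and Sqle at 0.41. For cholesterol synthesis, camera gave adjusted p = 0.00148, and adjusted p = 0.405 with an estimated correlation.

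Another 3 lists passed between Pax7 and Pax3 arrays, and lost their calls without replicate 3 of the Pax3 group. Satellite cell markers gave 3 rises, 9 falls and 13 not past of 25 (13 adjusted over the list alone), with Cav1 at -1.30, Fgfr4 at -0.82, the hepatocyte growth factor receptor Met at -0.61 and the chemokine receptor Cxcr4 at 0.74. For the satellite cell list, camera gave adjusted p = 0.0193, 0.0614 without that array, and adjusted p = 0.395 with an estimated correlation. Imprinted growth genes gave 3 rises, 8 falls and 12 not past of 23 (11 adjusted over the list alone), with Peg10 at -1.14, Sgce at -1.05, Grb10 at -0.93 and Igf2 at -0.80. For imprinted genes, camera gave adjusted p = 0.0183, 0.072 without that array, and adjusted p = 0.156 with an estimated correlation. Growth factor genes gave 15 rises, 4 falls and 20 not past of 39 (22 adjusted over the list alone), with the MAPK inhibitor Spry4 at 0.71 and Igfbp7 at -0.99. For the growth factor list, camera gave adjusted p = 0.0179, 0.0523 without that array, and adjusted p = 0.565 with an estimated correlation.

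The other 17 lists did not pass camera between Pax7 and Pax3 arrays (adjusted p from 0.0579 to 0.956). BMP and TGF-beta genes gave 13 rises and 7 falls of 32 (23 adjusted over the list alone), with the coreceptor Tgfbr3 at 1.03 and Fst at 0.81 beside Bmp4 and Bmp6. Unfolded protein and amino acid stress genes gave 3 and 5 of 30 (13), with Slc7a11 at 1.10 and Atf3 at -0.31. They passed camera with a trended robust prior, with only the compared groups and with array weights (adjusted p = 0.0219, 0.0231 and 0.0492), and without control replicate 1 or 3 or Pax7 replicate 1 (0.0304 to 0.0372). Hypoxia and glycolysis genes gave 3 and 2 of 22 (6), with the phosphofructokinase Pfkp at 1.21 beside Slc2a3. Interferon response genes gave 3 and 8 of 30 (11), with Isg20 at 2.09, Rtp4 at -0.79 and Ifih1 at -0.72, and Wnt genes 3 and 8 of 31 (11), with the receptors Fzd1 at 0.94 and Fzd8 at -0.60. Hox genes gave 2 and 6 of 35 (8), with Hoxd8 at -0.76 and Hoxb4 at -0.52, dermomyotome genes 5 and 8 of 26 (13), with Lix1 at 1.31 and Foxc2 at 1.26, and Id and Notch genes 5 and 3 of 25 (9), with Dtx4 at 0.57 and Notch1 at 0.51. Basement membrane and integrin genes gave 7 and 4 of 32 (14), with Itgb3 at 1.25, bone and cartilage genes 4 and 3 of 22 (7), with Acan at 1.61, and S phase genes 0 and 1 of 27 (1), with the ribonucleotide reductase subunit Rrm1 at -0.20. Adipocyte genes gave 3 and 2 of 21 (5), with Cd36 at -1.29, inflammatory cytokine genes 3 and 4 of 28 (7), with Cxcl12 at -0.95 and Il6 at 0.84, and neuronal and glial genes 5 and 1 of 28 (6), with Map2 at 0.60. Without Pax3 replicate 3 the neuronal and endothelial lists passed (camera adjusted p = 0.0243 each). Of the neuronal rises, Tubb3, L1cam and Gap43 lost their calls without Pax7 replicate 1 (limma adjusted p = 0.0583 to 0.11). Tubb3 and Gap43 also lost theirs without Pax3 replicate 1 (0.161 and 0.107) or either other Pax7 array, and L1cam without Pax3 replicate 2 (0.0754). The falls of the cytokine genes Ccl5 and Ccl7 lost theirs when any single Pax7 array was left out (limma adjusted p = 0.0715 to 0.114). Neural crest genes gave 2 and 3 of 25 (5), with Snai2 at -0.29, endothelial genes 2 and 0 of 18 (2), with Egfl7 at 0.42, and macrophage and leukocyte genes 1 and 1 of 20 (2), with Cd68 at 0.68 and Laptm5 at -0.59. Median and mean had different signs in the dermomyotome (0.00757 and -0.0129), Wnt (0.0142 and -0.0274) and Hox (0.0293 and -0.0604) lists, and camera placed the neural crest list downward with both above 0 (0.035 and 0.00263). Of the 10 lists past camera, 0 passed with an estimated correlation (6 of 27 at an unadjusted p under 0.05). Fry passed 15 of 27 but not the growth factor list (adjusted p = 0.0958), and it placed the neural crest list upward and the inflammatory list downward, each against camera and without a call.

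Changes in Pax3 and Pax7 arrays largely went the same way. Of the genes past the threshold in both comparisons against control, 6548 changed in the same direction (3195 higher and 3353 lower) and 82 in opposite directions. Without Pax3 replicate 3, 124 changed in opposite directions, and with array weights 147 did. Besides Xist and Eif2s3y, the largest shared changes were in Prl2c5, Nefl and Cxcl13, all far beyond their standard errors. Independent lists of these sizes would share 1679 genes in the same direction, 844 higher and 835 lower, and as many in opposite directions. Unchanged groups simulated with 3 shared control arrays had on average 0.01 genes in common in 100 simulations. Almost no gene passes where none is changed, so this count is no baseline for lists of this length. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.916 (Spearman 0.848), against 0.501 in the simulation, and 82.5% of genes had the same sign, against 66.7%. Their covariance was 0.259, against 0.00211 simulated, a difference of 0.257. With 3 control arrays the controls could not be split into parts of at least 2. The simulation covered only the random spread of shared controls, not a difference between the control cells and all Pax cells. The split of the sex-linked genes was common to both comparisons. The shared changes and the correlation can therefore come, in part or in whole, from such a difference between cells or animals. An effect common to both factors cannot be told apart from it.

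Among the 6548 shared changes, 2040 also differed between Pax7 and Pax3 arrays (limma adjusted p under 0.05), and 1569 of these (76.9%) lay further from control in Pax7 arrays. Of the genes higher in both, 868 were further in Pax7 and 313 in Pax3 arrays; of those lower in both, 701 and 158. Slc2a3, Bmp4 and Bmp6 were further up in Pax7 arrays, and Myl1, Car3 and Dio2 further down, while Grb10 (3.38 and 2.45), Hoxd8 (3.66 and 2.89) and Sim2 (4.15 and 3.71) were further up in Pax3 arrays. The median absolute log2 fold change over the shared changes was 0.42 in Pax3 and 0.47 in Pax7 arrays. Without replicate 3 of the Pax3 group, the most variable array, the share further in Pax7 was 72.1%, and over all arrays left out in turn it ran from 72.1% to 80.6%.

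**Figure D4:**
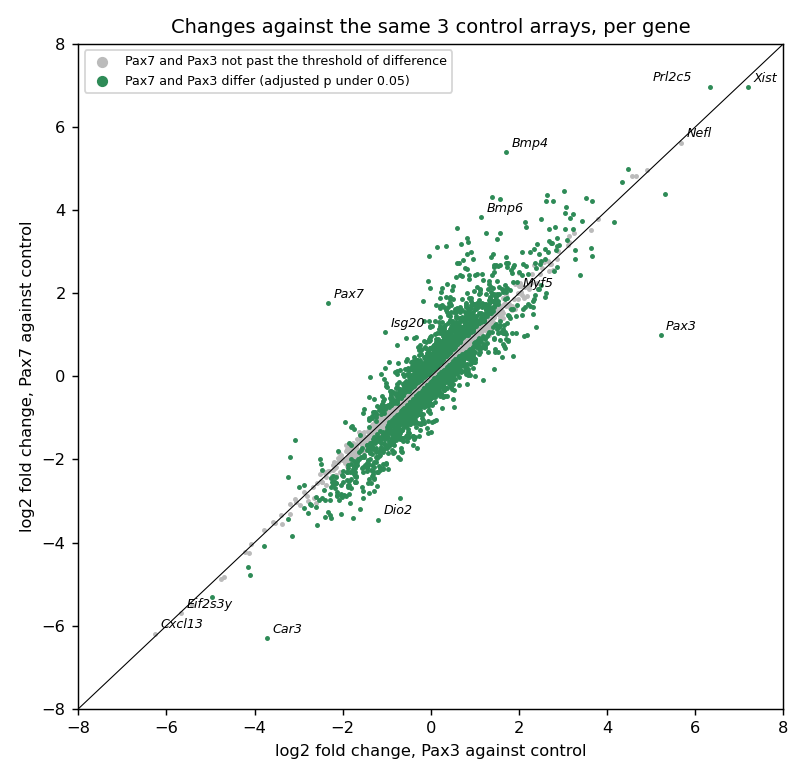
Log2 fold change against control of each of 19661 genes in Pax3 arrays (horizontal axis) and Pax7 arrays (vertical axis), with the line of equal change; green points differed between Pax7 and Pax3 arrays (limma adjusted p under 0.05) and grey points did not pass. Most genes lie along the line (r = 0.916), with Xist, Prl2c5 and Nefl at the upper end, Cxcl13 and Eif2s3y at the lower end, and Pax3, Pax7, Bmp4 and Car3 far from it.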

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

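The genes in this part were picked by fixed rules, and only the alternatives for the count of genes in opposite directions were chosen after the result was seen. Groups of 3 arrays are too small for the check for single arrays far from the others. In the comparison of Pax7 with Pax3 arrays, 82 genes that had changed in opposite directions against control differed, all of them past the limma threshold. The comparisons share the same standard error per gene, so calls of opposite sign against control add up in this difference. These genes therefore had to pass, which is no further evidence. The number of genes in opposite directions ran from 56 (without control replicate 1) to 124 (without Pax3 replicate 3) with single arrays left out and was 147 with array weights. Pax7 itself differed most (log2 difference 4.09 ± 0.053, SE, n = 3 per group), at -2.33 against control in Pax3 and 1.77 in Pax7 arrays. Isg20, an interferon-induced exonuclease, differed by 2.09 (-1.03 and 1.07 against control, limma adjusted p = 2.3e-09). The secreted protein gene Nell2 differed by 2.00 (-0.18 and 1.82), with a call in Pax3 arrays (adjusted p = 0.0176) that ended without control replicate 3 or Pax3 replicate 1, at an adjusted p of up to 0.0699. The sodium pump subunit Atp1b1 differed by 1.54 (-0.77 and 0.76), and the mitochondrial carrier Slc25a13 by 1.49 (-0.57 and 0.92). No biological explanation was tested.

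Probe sets that carried no gene name, 4659 in all, lay outside the comparisons of the report. Among these, 30 passed the limma threshold with a rise of at least 1 log2 unit in Pax3 arrays and 45 in Pax7 arrays, above the level of the control arrays. In all, 769 of them passed in Pax3 and 928 in Pax7 arrays against control, and 200 between Pax7 and Pax3 arrays. What these probe sets measure was not examined.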

How the results depend on the processing

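All alternatives for the share further in Pax7 and for the count of genes in opposite directions, array weights included, were chosen after seeing the data; those for the other results were fixed before. Counts at stricter settings fell because fewer genes can pass. With a change of at least 1 log2 unit, 944, 1294 and 176 genes passed for Pax3 against control, Pax7 against control and Pax7 against Pax3. In limma's treat test at 1.2-fold, 3264, 3819 and 784 passed. At an adjusted p under 0.01, 2107 passed between Pax7 and Pax3. Weighting the arrays raised the count between Pax7 and Pax3 from 3316 to 5348 moved the share further in Pax7 from 76.9% to 69.5% and the count in opposite directions from 82 to 147, and the cause was not tested.

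With an estimated correlation camera passed 0, 0 and 0 lists (8, 8 and 6 at an unadjusted p under 0.05). The estimate lay far above the preset of 0.01 in some lists, such as sarcomere (0.362) and G2 and M phase genes (0.351). It lay below the preset in imprinted growth (-0.0317) and Hox genes (-0.00591), which also lost their calls. A higher correlation therefore does not account for every lost call, and what else contributed was not tested. Fry passed 25 lists for Pax7 against control and turned the BMP and TGF-beta list upward (adjusted p = 0.00365), and the cause was not tested.

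Arrays left out in turn gave 6903 to 7753, 7519 to 9253 and 2507 to 4277 genes, 5837 to 6507 shared genes, 56 to 124 genes in opposite directions (124 without Pax3 replicate 3), r = 0.907 (without Pax3 replicate 3) to 0.918, and a share further in Pax7 of 72.1% to 80.6%.

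The replicate numbers did not pair the arrays. Deviations of same-number arrays correlated at -0.026 to 0.225, with 3 of 9 pairs over 0.1, those of different numbers at -0.247 to 0.246, and 4 of 9 arrays lay closest to their own number. The replicate block gave 7902, 8707 and 3328 genes and 6662 shared, and the dermomyotome list passed for Pax7 against control (camera adjusted p = 0.0373).

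The 380 results for named genes were each counted once per setting, so the same gene can count several times. Counted so, other settings ended 10 calls, added 4 and left 3305 results the same. Arrays left out ended 75, added 3 and left 3342 the same, and 0 reversed. For gene lists, counted once per list, comparison and setting, other settings ended 45 calls, added 35, reversed 1 and left 810 the same. The 45 include every list call, since 0 lists passed with an estimated correlation. Arrays left out ended 3 list calls, added 12 and left 714 the same. Centring each array on its median moved the share of higher calls from 49.4% to 56.4% between Pax7 and Pax3 and from 50.2% to 44.6% for Pax3 against control. Signal over background limits genes near the lowest intensities.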

Other observations

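Tests of the sex-linked genes, of swapped arrays, of the source of the cells, of the share of muscle cells, of dividing cells, of Pax3 replicate 3 and of the value distribution were chosen only after the result was seen, as were the 2 gene lists of this part; the tests of the splits were not. Genes of the lysosome were higher in both Pax groups. After Gpnmb (3.66 in Pax3 and 4.22 in Pax7 arrays) and Cd68 had been seen among the rises, a list of 26 measured lysosomal genes that left both out was tested. Against control, 18 rose, 2 fell and 6 did not pass in Pax3 arrays (22 adjusted over the list alone), and 22 rose, 0 fell and 4 did not pass in Pax7 arrays (22). The hydrolases Hexa (1.40 and 1.67), Gla (1.37 and 1.65) and Manba (1.68 and 2.07) and the proteases Ctsb (0.78 and 0.88) and Ctsl (0.70 and 0.84) were among the rises. Camera, adjusted over the 2 lists of this part, gave adjusted p = 2.58e-06 in Pax3 and 2.21e-09 in Pax7 arrays, and adjusted p = 0.0239 and 0.0084 with an estimated correlation. Between Pax7 and Pax3 arrays, 15 rose, 0 fell and 11 did not pass (17 adjusted over the list alone; camera adjusted p = 2.69e-09, and adjusted p = 0.00861 with an estimated correlation). The lists fixed beforehand were adjusted over more lists, so these adjusted p-values cannot be compared with theirs. Unadjusted, camera with an estimated correlation gave lysosomal genes p = 0.012 in Pax3, 0.0042 in Pax7 and 0.0043 between Pax7 and Pax3 arrays. The lowest such p of a fixed list was 0.0075, 0.0087 and 0.0047 in that order (adjusted p = 0.098, 0.108 and 0.104). A rise of lysosomal genes as a group may accompany both factors, but this rests on a list chosen after the data were seen. Against control the rise cannot be separated from the sex-linked split.

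Rises of the epithelial junction and keratin genes Dsp (4.57 and 4.83), Cxadr (3.04 and 3.54), Perp (0.60 and 2.72) and Krt18 (0.66 and 2.44) prompted a list that left these 4 genes out. Of 33 measured, 9 rose and 3 fell in Pax3 arrays (11 adjusted over the list alone) and 10 rose and 4 fell in Pax7 arrays (14). Jup (1.17 and 2.47), Esrp2 (0.87 and 2.43) and Spint1 (0.80 and 1.76) rose, and Pkp2 (-0.63 and -0.87) fell. The list did not pass camera against control (adjusted p = 0.340 and 0.0627). It passed between Pax7 and Pax3 arrays with 7 rises and 2 falls (10 adjusted over the list alone; adjusted p = 0.000776, and adjusted p = 0.171 with an estimated correlation).

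Control arrays held Y-linked transcripts and little Xist, and all Pax3 and Pax7 arrays the reverse. Loss of the Y chromosome in the Pax cultures would leave Xist low, but Xist was higher by at least 6.96 (SE 0.0642). A swap of arrays, or of whole groups, between control and Pax cells would put low Pax3 or Pax7 under a Pax label, but the lowest array of the overexpressing group lay at least 1.65 above the highest other array for Pax7 and 4.14 for Pax3. A median rise of at least 0.233 (0.335 in the other comparison) over Kdm6a, Kdm5c, Eif2s3x, Pbdc1 and Ddx3x, genes that escape X inactivation, may mean that control cells came from a male and the Pax cells from female animals. Ddx3x moved least, by 0.15 in Pax3 arrays (limma adjusted p = 0.0287, up to 0.0991 under other settings and with single arrays left out) and by 0.03 in Pax7 arrays (adjusted p = 0.64).

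Sarcomere genes were lower in both Pax groups than in control (medians -1.07 and -1.72), and an effect of Pax3 or Pax7 cannot be told apart from a difference between the animals the cells came from, since no array held female cells without either factor. They were lower in Pax7 than in Pax3 arrays as well (median -0.67), where Xist, Kdm5d, Eif2s3y and Uty differed by at most 0.240, which argues against a difference of sex. A lower share of muscle cells would lower myoblast genes as far. Myod1 (-0.32), Myf5 (0.05), Cdh15 (0.09), Itga7 (-0.23) and Des (-0.81) had a median of -0.227 (SD 0.363), and Des fell further than the sarcomere median. These genes do not decide the question. Myod1, Itga7 and Des fell (limma adjusted p at most 0.00173), while Cdh15 and Myf5 did not pass. Myf5 was also raised against control in both Pax groups (1.97 and 2.02), so it may not follow the share of muscle cells. More dividing cells would raise S phase and G2 and M phase genes, whose medians were -0.0404 and -0.0915. An effect of the overexpressed factor on differentiation may explain the difference between Pax7 and Pax3 arrays and stays a hypothesis. A difference between animals or cultures of the same sex cannot be told apart from it, since the labels do not give the animal of the cells.

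Shared changes lay further from control in Pax7 than in Pax3 arrays in 76.9% of the genes that differed. Without the more variable Pax3 replicate 3 the share was 72.05%, and after a further quantile normalisation 75.1%, which argues against that array and against a wider value distribution as the whole cause. No biological explanation was tested. Different levels of the 2 introduced factors stay open, as does a difference between the animals or cultures of the groups.

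With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 7780 genes for Pax3 against control, 8485 for Pax7 against control and 3316 for Pax7 against Pax3, the highest other split gave 0 in each (limma), and 1 of 10 gave as many. For gene lists past camera the real splits gave 15, 14 and 10 and the highest others 9, 10 and 9, and again 1 of 10 gave as many. Among 100 splits of the 9 arrays, the real split included, only the real split reached 6548 shared genes in the same direction (highest other 5959). The other splits mostly mixed groups that differ widely, and the arrays of a group can be technical repeats. The result therefore says nothing about chance between cultures or animals. For the correlation of the log2 fold changes, 30 of 100 gave at least the real 0.916 (highest other 0.984). In 26 of these the group taken as control held Pax arrays, which puts the difference between control and Pax arrays into both fold changes, so this count decides nothing about chance.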
